A study of Caenorhabditis elegans with 6 samples.

How the data were processed

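Peak lists of 3 RIP-seq replicates of L4 larvae with 3xFLAG-tagged MBL-1 were analysed, each from 1 anti-FLAG IP and the RNA input of the same number. RNA was fragmented to 250 bp and sequenced as paired reads of 150 nt, per the labels' protocols. Samples were grouped as RNA input and anti-FLAG IP from the sample titles. The submitters' processing notes name BWA, MACS2, DiffBind and the build WBcel235, without versions. Peaks were called by the authors with MACS2 2.1.0.20150420 on 1 IP and 1 input at a time, without pooling, per the file headers, with a p threshold of 0.001, no shifting model, extension of tags to 201 to 203 bp, summits called within peaks, and an effective genome of 33769074 bp. The names of the alignment files carry the abbreviations uni and dedup, and 1 tag was kept per position, per the file headers, which removed 67 to 72% of tags.

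The deposited lists give 4 quantities per summit. The signal is the pileup, the coverage of extended IP tags at the summit, which the authors' caller scaled to the smaller library. The fold enrichment is the authors' ratio of IP pileup to the local input level, each with 1 added. The −log10 p and −log10 q are the Poisson values of the authors' caller, and the headers say that q was not calculated although the deposited −log10 q column holds values. These are the authors' values for each peak. Pileup divided by the scaling factor gave whole IP tags at all summits within 0.02, and the local input level was recovered from pileup and fold. Where that level lay within 0.01 of the genome-wide background, the input had about 1 tag or none within 1000 bp, and the fold has no measured denominator.

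Peaks of different lists were shared when they overlapped by at least 1 bp, and overlapping peaks were merged into regions. The fold of a region in a list is that of its strongest peak. Genes were taken from a RefSeq gene table of the same assembly, with 31563 genes after piRNA genes were left out. Genes were named by position of the summit, with small structured RNA genes (snoRNA, snRNA, rRNA, tRNA, scRNA and microRNA) before the protein-coding genes that hold them. The build was matched by name alone, WBcel235 in both the submitters' processing notes and the gene table. The table has no strand, exons or sequence. The planned placement on exons was therefore made on gene bodies, the planned annotation by UTR, coding sequence and intron was replaced by gene class, and the planned test of the YGCY motif was not run.

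Sharing was tested one-sided against 1000 random placements on gene bodies, and within genes against 1000 random placements in each peak's own gene, introns included, which understates the overlap that exon-derived reads give by chance. The class of summits was tested two-sided against 1000 random summits in the same genes. The 15 fixed gene lists were compared with Fisher's exact test and Benjamini-Hochberg adjustment over the lists that had a gene with a peak, since only genes with a peak could recur and expression was not used. Fold enrichments of shared regions were described with means, SDs and correlations across regions, with 1000 bootstrap draws, and no difference between groups was tested. The named genes were fixed before the data were examined as up to 25 genes at regions in all 3 lists ranked by their lowest fold, mbl-1, up to 4 recurrent members of each fixed list (or members in 1 list where none recurred), and the 3 highest peaks of each list. B0412.6 qualified by its region, although the summit of list 3 there fell on the neighbouring B0412.7.

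Region building and the test of sharing were tried on simulated lists of the real sizes. All 60 planted shared regions were recovered in all 3 lists, which planting them at nearly the same place made certain. For sharing, 0 of 20 unrelated list pairs reached p under 0.05. The test within genes was simulated on longer coding genes with 1 peak per list. There 1 of 20 simulations with unrelated places reached p under 0.05. Those places were drawn as in the test itself, so the simulation does not show how the test handles exon-derived reads. Alternatives were stricter thresholds on q and fold, other overlap rules, placement on the whole genome, other annotation rules and leaving out each replicate. After the data were seen, a q of at most 0.05, genes of at least 1000 bp, and leaving out mbl-1 or lin-1 were added. Recurrence by gene class was also compared at like IP tag numbers with 4 hand-set bins and then, after that result was seen, with decile bins, and later by the tags of each list alone, and all are given. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 with fixed seeds.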

Results

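RNA bound by the splicing regulator MBL-1, the Caenorhabditis elegans muscleblind protein, was sampled by RNA immunoprecipitation and sequencing (RIP-seq) from whole L4 larvae. The animals carried a 3xFLAG tag on MBL-1, under the genotype mbl-1c(syb5299) in the labels, and were grown at 20 °C. The 6 samples fell into 2 groups of 3, total RNA before precipitation (RNA input) and RNA recovered with an anti-FLAG antibody (IP). The comparison asks which transcripts were enriched by the precipitation over the input. One peak list was used per replicate, each holding the regions in which an IP exceeded the input of the same number, and these are called lists 1, 2 and 3. The labels do not state that replicates came from separate cultures, so recurrence between lists describes only these samples, whose spread may be technical. The p-values have peaks, regions or genes as their units and do not measure the spread between samples. An IP from animals without the tag was not analysed here.

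The libraries behind the lists were shallow. After the removal of tags at the same position, IP 1, IP 2 and IP 3 contributed 39033, 49827 and 41840 tags, and inputs 1, 2 and 3 contributed 36643, 38364 and 30707 tags. Lists 1, 2 and 3 held 106, 143 and 188 peaks, with median fold enrichments of 5.84, 5.54 and 4.56 as the authors' caller gave them. The median peak rested on 11, 12 and 7 IP tags at its summit, and 11 tags have a 95% Poisson interval of 5.49 to 19.7, which covers counting error only. At 264 of the 437 peaks the input level was the genome-wide background, so that the fold there was set by the IP tags, the background and an added constant of 1 and was not a measured ratio. In list 3, 83 of 188 peaks had a q over 0.05, against 9 of 106 in list 1 and 29 of 143 in list 2.

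Enriched regions recurred between the replicates at snoRNA genes, at mbl-1 itself and at a set of other protein-coding genes. Merging overlapping peaks gave 255 regions, of which 64 were in all 3 lists, 51 in 2 lists and 140 in 1 list. In list 1, 77 of 106 peaks overlapped a peak of list 2 and 77 overlapped a peak of list 3, and 91 of 143 peaks of list 2 overlapped a peak of list 3. Random placement of the peaks on annotated gene bodies gave at most 2, 2 and 3 overlaps for these pairs (one-sided permutation test, p = 0.001 for each, adjusted p = 0.001, the smallest that 1000 placements can give). Random placement does not account for expression, since abundant transcripts are sampled in every library. Position within genes was tested as well, with introns among the random places because exons were not used. Reads of a spliced mRNA fall on its exons alone, so overlap above this random level arises without binding, and the test does not separate enrichment from transcript structure. Among 502 pairs of peaks from different lists in the same gene, 244 overlapped, against a mean of 163.9 and a maximum of 185 when each peak was placed at random in its own gene (one-sided permutation test, p = 0.001). Of these, 125 pairs lay in genes under 1000 bp, where all 125 overlapped and a mean of 124.7 did so at random, so that the test says nothing about position in such short genes, snoRNA genes among them. In genes of at least 1000 bp, a threshold chosen after the data were seen, 35 pairs of lists 1 and 2, 38 of lists 1 and 3 and 46 of lists 2 and 3 overlapped, against random means of 11.6, 12.6 and 14.8 (one-sided permutation test, p = 0.001 for each). Regions in 1 list had a median of 5 IP tags, those in 2 lists 7.5 and those in 3 lists 17. At a stricter −log10 q of at least 5, 35 regions were in all 3 lists.

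Regions in all 3 lists were ranked by the lowest of their 3 folds. The first lay in the protein-coding gene Y55B1BL.1 (WBcel235, chromosome III, 403382 to 404388), with a fold of 48.1 ± 5.73 (SD, n = 3) over input at background in each list. A neighbouring region of the same gene (405065 to 405458) reached 23.6 ± 3.66 (SD, n = 3). Of the other genes, the next in this ranking were snoRNA genes, which encode small nucleolar RNAs that guide modification of ribosomal and spliceosomal RNA. F11A10.9, within rbm-34 (IV, 12086599 to 12086962), had a fold of 29.1 ± 5.58 (SD, n = 3), ZK643.9 (III, 8937668 to 8938026) 27.7 ± 5.52 (SD, n = 3), Y23H5B.10 (I, 2514048 to 2514433) 22.2 ± 10.5 (SD, n = 3) and C05D2.15, within madf-11 (III, 5601931 to 5602276), 20.6 ± 4.06 (SD, n = 3). Input was at the background in each list for F11A10.9, ZK643.9 and C05D2.15, so these folds have no measured denominator. At Y23H5B.10 this held in lists 1 and 3 but not in list 2. Its folds were 33.1, 12.1 and 21.3 in lists 1, 2 and 3, from 42, 46 and 33 IP tags. Further snoRNA genes among the 25 ranked highest by their lowest fold were C10C6.8, T24H7.6, C06A1.8, W08G11.6, Y53F4B.48, ZK632.18, K09E9.5, K07C11.11, R166.7, T04A8.17, Y74C9A.6 and B0412.6, and the snRNA genes were F08H9.10, F10D2.13 and F11A5.14. Their mean folds lay between 6.37 at B0412.6 and 16.9 at C06A1.8. The coding genes F09E10.7 (X, 1500248 to 1500967) and T28F4.4 (I, 7491975 to 7492445) had folds of 11.8 ± 1.21 and 8.27 ± 1.58 (SD, n = 3). Those of F09E10.7 were over input at background in each list. The strongest region of egl-8, which encodes a phospholipase C beta (V, 31801 to 32209), had 9.78 ± 2.98 (SD, n = 3), and 3 of the 5 regions of egl-8 were in at least 2 lists.

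**Figure D1:**
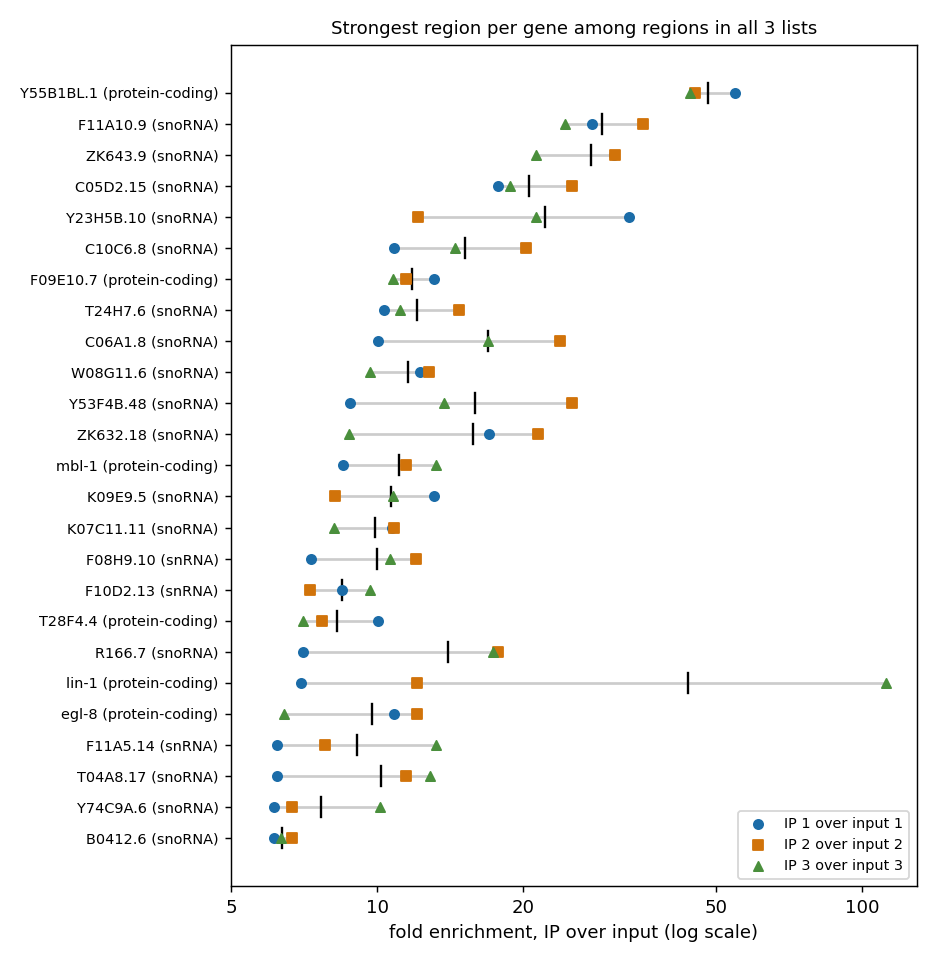
Fold enrichment of IP over input (x axis, log scale) for the strongest region of each of the 25 genes ranked highest by the lowest of their 3 folds among regions in all 3 lists. Points are the 3 lists, grey lines their range and black ticks their mean. Y55B1BL.1 lies between 44.2 and 54.7, and lin-1 reaches 112.1 in list 3 alone.

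Fold enrichments were similar in rank between lists. Across the regions shared by a pair, Spearman's rho was 0.628 for lists 1 and 2 (76 regions), 0.642 for lists 1 and 3 (77 regions) and 0.738 for lists 2 and 3 (90 regions), and Pearson's r of log2 folds was 0.73, 0.64 and 0.76. These describe regions above a calling threshold, and regions are not independent replicates. In the 64 regions of all lists the median coefficient of variation of the fold was 23.1%, and 19 had a mean fold of at least 10. The gene lin-1, which encodes an ETS-domain transcription factor (IV, 2276866 to 2279328), had folds of 6.97, 12.1 and 112.1. Its peak in list 3 was 2463 bp wide with 5 summits and 213 IP tags, against 8 and 18 tags in lists 1 and 2. Without lin-1, Pearson's r of lists 1 and 3 was 0.73.

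RNA from the gene of the tagged protein was enriched at several places. In mbl-1 (X, 16978608 to 17010300) 8 regions were found, 6 of them in all 3 lists and 2 in lists 2 and 3. They lay between 17001596 and 17010076, in 26.8% of the annotated gene at its high-coordinate end, and none lay in the 22988 bp of the gene before the first region. The strongest (17001596 to 17001946) had a fold of 11.1 ± 2.39 (SD, n = 3), from 10, 17 and 20 IP tags, and the region at 17008094 to 17008401 had 7.81 ± 1.43 (SD, n = 3). The lowest fold of the 6 was 4.96 ± 1.85 (SD, n = 3) at 17008657 to 17009124. Of the 22 mbl-1 peaks, 21 had an input level at the background, so that their folds have no measured denominator. The next highest number of regions in all 3 lists in a coding gene was 3, in Y55B1BL.1. Exons and strand were not used here, so whether these regions are exonic, intronic or in a UTR is not given.

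**Figure D2:**
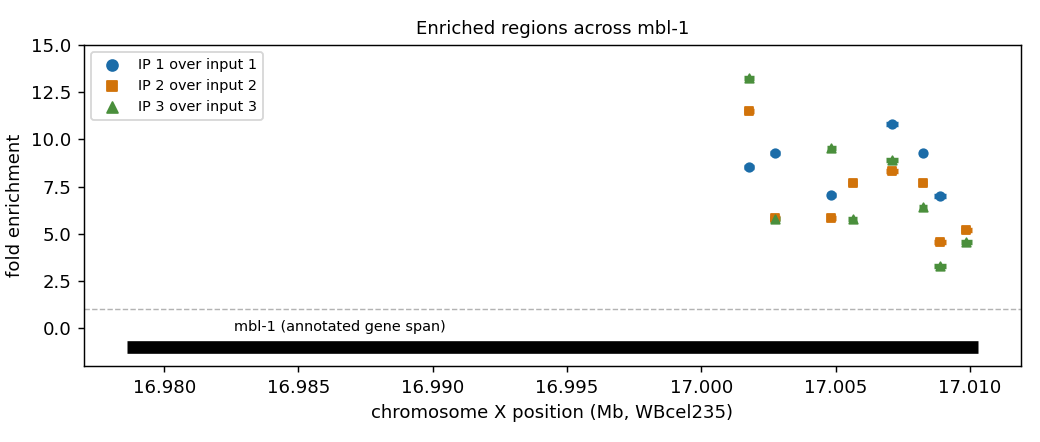
Enriched regions across mbl-1 on chromosome X (WBcel235, x axis in Mb). Each symbol is a region's fold enrichment in 1 list (y axis), drawn at the middle of the region with a bar for its width, the dashed line marks a fold of 1 and the black bar the annotated gene. The 8 regions lie between 17001596 and 17010076.

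By gene class at the summit, regions recurring in at least 2 lists lay at small structured RNA genes and at protein-coding genes. Of 115 such regions, 46 lay at small structured RNA genes (40%, exact Clopper-Pearson 95% interval 30.98 to 49.55%), 63 at 47 protein-coding genes (54.8%), 5 at other non-coding RNA genes and 1 at a pseudogene. Random summits within the same genes gave a mean of 21.9 and a maximum of 27 regions at small structured RNA genes (two-sided permutation test, p = 0.002, the smallest that 1000 placements can give). This test rests on small structured RNA genes that lie inside other genes and does not account for the abundance of either RNA. Among the 46 were 33 snoRNA and 11 snRNA regions, 1 at the annotated entry of the microRNA gene let-7 and 1 at a mitochondrial rRNA. Of these 46, 27 lay inside a protein-coding gene, where RNA of the host cannot be told apart from the small RNA without strand and exons. When the largest overlap of the whole peak named the gene, in place of the summit, the share was 13.04%. Among regions in 1 list, 9 of 140 lay at small structured RNA genes and 126 at protein-coding genes.

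**Figure D3:**
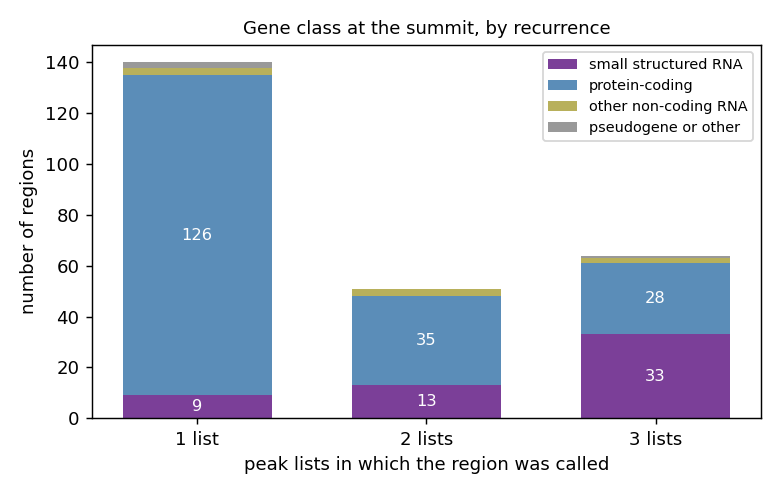
Number of regions (y axis) by the number of lists in which they were called (x axis), coloured by gene class at the summit. Regions at small structured RNA genes number 9 in 1 list, 13 in 2 lists and 33 in 3 lists, and those at protein-coding genes 126, 35 and 28.

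Of the 198 genes with a peak, 108 had one in at least 2 lists and 59 in all 3, and 132 of the 198 were protein-coding. Of 15 gene lists fixed before the data were examined, only those with a gene that had a peak were tested. Among them, 1 differed from the other genes with a peak in how often its members recurred. In the structured non-coding RNA list, 45 of 55 genes with a peak had one in at least 2 lists, against 63 of 143 other genes (Fisher's exact test, two-sided, p = 1.25e-06, adjusted p = 1.25e-05 by Benjamini-Hochberg). The same comparison at −log10 q of at least 5 gave an adjusted p of 0.13. Neither comparison takes IP tag number into account. Regions at small structured RNA genes had a median of 19 IP tags, against 6 at protein-coding genes. All 4 body wall muscle genes with a peak were in at least 2 lists (Fisher's exact test, adjusted p = 0.637), but without replicate 2 this held for 2 of 4, at a q of at most 0.05 for 2 of 3, and at −log10 q of at least 5 for 0 of 1. They were lev-11, which encodes tropomyosin, with a fold of 5.59 ± 1.29 (SD, n = 3) at I, 14623384 to 14623840, the actin gene act-4 with 5.04 ± 0.605 (SD, n = 3), and the myosin light chain genes mlc-1 (4.25 in list 2, 3.51 in list 3) and mlc-3 (2.83 in list 1, 2.48 in list 2). The peaks of mlc-1 and of mlc-3 did not overlap between lists.

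Of the neuron list, 7 genes had a peak and 3 had one in at least 2 lists (Fisher's exact test, adjusted p = 1). The alpha-tubulin gene mec-12, used in touch receptor neurons, had 5.79 ± 1.20 (SD, n = 3) at III, 3131635 to 3132031. The calcium/calmodulin-dependent kinase gene unc-43 had a peak in each list, with folds of 3.90, 4.57 and 3.94 at up to 6 tags, where the peak of list 2 did not overlap those of lists 1 and 3, and the beta-tubulin gene mec-7 had 4.57 in list 2 and 6.43 in list 3. Of the cytoskeleton and adhesion list, 4 of 5 genes were in at least 2 lists (Fisher's exact test, adjusted p = 1), with tba-1 at 5.42 ± 1.19 and tbb-2 at 4.34 ± 0.145 (SD, n = 3), together with the spectrin gene unc-70 and the spectraplakin gene vab-10. The shared region of unc-70 (V, 6889678 to 6890148) had folds of 5.44 in list 1 and 2.70 in list 3, and its peak in list 2 lay elsewhere. The shared region of vab-10 (I, 11774208 to 11774522) had 3.38 in list 1 and 4.57 in list 2.

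Of the RNA-binding protein and splicing regulator list, 5 genes had a peak and mbl-1 and pab-2 had one in at least 2 lists (Fisher's exact test, adjusted p = 1), with pab-2 at 5.44 in list 1 and 3.07 in list 3. The other 3 were the splicing regulators sup-12, fox-1 and asd-2, named after their values were seen, each in list 3 alone. In the microRNA list, a region at X, 14743631 to 14743832, had folds of 5.20 in list 2 and 3.32 in list 3, from 7 and 4 tags with input at the background. It lay in the let-7 entry of 1732 bp (14743590 to 14745321), inside C05G5.7, and the microRNA itself was not located within that entry. The other lists held cgh-1 of the germline list (5.44 in list 1, 2.70 in list 3, at places that did not overlap), cct-5 of the heat shock and chaperone list (3.19 in list 2, 4.21 in list 3), where cct-7 had a peak in list 1 alone, elt-2 of the intestine list (7.67 in list 3) and the mitochondrial rRNA KEF34_r02 (1.78 in list 1, 2.07 in list 2). For these lists the adjusted p of Fisher's exact test was 1. No gene of the pharyngeal muscle, cuticle collagen and hypodermis, ribosomal protein, translation factor or histone lists had a peak named at its summit, and these were not tested. Only 132 of 19983 annotated coding genes had a peak, so these absences carry little information about the lists. When every gene overlapped by a peak was counted, 3 ribosomal protein genes were in at least 2 lists.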

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

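The thresholds of q at most 0.05, genes of at least 1000 bp, and the omission of mbl-1 or lin-1 were chosen after seeing the data, and the other alternatives before. The permutation tests of sharing and of position within genes gave p = 0.001 throughout, the smallest possible, so the counts are given in its place. Sharing between lists was 39 to 91 peaks against at most 3 in any placement under reciprocal overlap, the summit rule, both stricter thresholds, q at most 0.05 and placement on the whole genome, and within genes the observed pairs were 1.39 to 3.03 times the random mean under reciprocal overlap, in longer genes, without mbl-1 and without each replicate, all against a random level that includes introns. Spearman's rho stayed between 0.622 and 0.782 over pairs and alternatives. Counts moved with the threshold. At −log10 q of at least 5, lists 1, 2 and 3 held 52, 62 and 59 peaks, 51 regions were in at least 2 lists and 35 in all 3. A fold of at least 4 and a q of at most 0.05 each left 105 peaks in list 3. These lower counts follow from the filters' own construction. At −log10 q of at least 5, 0 fixed gene lists passed. There 33 of 46 structured non-coding RNA genes recurred against 14 of 32 other genes (Fisher's exact test, adjusted p = 0.13), with fewer genes tested than in the main comparison, and the cause was not tested. Leaving out each replicate gave 76 to 90 regions shared by both remaining lists, which is fewer by construction. The share of regions at small structured RNA genes was 13.04% by largest overlap, for which no random placement was made. That rule favours a long host gene over a small gene inside it. Only 27 of the 46 regions lay inside a protein-coding gene. The drop from 40% to 13.04% of 115 regions is larger than these 27, so coding hosts do not cover the whole of it. The cause of the drop was not tested. Under the other alternatives the share was 30.7 to 51.6%, each above the random mean. Of 42 named genes, 24 kept their number of lists at −log10 q of at least 5 and 11 had no peak left, while 32 kept it at fold of at least 4 and 32 at q of at most 0.05. The planned tests of the YGCY motif, with their alternatives, and of UTR, coding and intron positions were not run, since sequence and exons were not used here. No paired analysis was possible because the lists give values only where a peak was called, and no test between groups was made. The folds are already ratios within pairs, and testing them against no enrichment would be decided by the calling. Regions in 1 list rested on a median of 5 tags, which limits what their absence from another list shows.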

Other observations

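All tests in this part were chosen after the results were seen. Several genes of the vacuolar proton pump and of tubulin were among the names with a peak. Of 20 annotated vha genes, which encode subunits of the vacuolar ATPase, 6 had a peak in some list (vha-2, vha-3, vha-5, vha-8, vha-11 and vha-16), against 0.132 for random coding genes (exact hypergeometric test, p = 2.66e-09), but only vha-16 had one in at least 2 lists. Without list 3 the count was 2, at a q of at most 0.05 or a fold of at least 4 it was 3, and at −log10 q of at least 5 it was 0. Of 16 tubulin genes, 5 had a peak (ben-1, mec-7, mec-12, tba-1 and tbb-2), against 0.106 at random (exact hypergeometric test, p = 4.80e-08), and all 5 had one in at least 2 lists. At −log10 q of at least 5, 4 tubulin genes had a peak and 1 had one in at least 2 lists. Both families were picked from the names with a peak, and random genes do not match their expression, so these p-values overstate the evidence. The X chromosome held 23.8% of regions at coding genes and 15.5% of coding gene length (exact binomial test, adjusted p = 0.020 over 6 chromosomes). Without mbl-1 the share was 20.4% (exact binomial test, adjusted p = 0.364). Both tests count several regions of 1 gene as independent. By gene, X held 28 of 132 coding genes with a peak (21.2%) and 13.7% of annotated coding genes (exact binomial test, adjusted p = 0.077). Without mbl-1 it held 27 of 131 (exact binomial test, adjusted p = 0.075).

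Regions at small structured RNA genes recurred in at least 2 lists more often than regions at protein-coding genes, 46 of 55 against 63 of 189 (Fisher's exact test, p = 3.52e-11). The 189 coding regions lay in 132 genes, and the test counts regions of 1 gene as independent, so its p-value may overstate the evidence. By gene, 31 of the 132 had a peak in exactly 2 lists and 24 in all 3. Regions at small structured RNA genes also had more IP tags, with a median of 19 against 6. Permuting gene class within bins of the highest IP tag number raised the number expected from 24.6 to 41.1 of the 46 with 4 hand-set bins (two-sided permutation test, p = 0.0343) and to 42.7 with 9 decile bins (p = 0.171), where the deciles were chosen after the first result had been seen. That number is a maximum over more lists for recurrent regions, so these bins partly follow recurrence, and the tags of each list alone were then used in the same permutation test, which gave p = 0.183, 0.109 and 0.0653 for lists 1, 2 and 3 with the 4 bins and 0.252, 0.249 and 0.054 with deciles. The observed number exceeded the expected one in all 8 permutation tests and passed the threshold in 1. The 8 tests reuse the same regions and are not independent, so their common direction adds little. Whether any excess is left beyond the tags depends on the test and stays open. Carry-over of abundant RNA by the precipitation may also contribute and cannot be told apart from binding, since no untagged IP was analysed here, and input was at the background for 35.8% of peaks at small structured RNA genes and 72.9% at protein-coding genes.

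The 6 regions of mbl-1 in all 3 lists were more than the length of the gene alone gives, since 1000 random placements of the 64 regions put at most 1 in mbl-1. The placements treat regions of 1 transcript as independent and take no account of expression. They therefore bear on gene length alone. A candidate explanation for the 6 regions is capture of mbl-1 mRNA through the tagged protein being made on it, and binding of MBL-1 to its own transcript is another. They cannot be told apart here, since exons and strand were not used. Both act through the tagged protein, so an untagged IP would not separate them. Such an IP would show enrichment that arises without the tag, and none was analysed here.

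The fold of lin-1 in list 3 exceeded the mean of lists 1 and 2 by 3.55 on the log2 scale. A general difference of list 3 is argued against by the other 63 regions in all 3 lists, whose median was -0.15 and whose highest value was 1.08. Material present in IP 3 alone may account for the 3.55 and cannot be told apart from a biological difference of that sample, since reads were not analysed. No biological explanation was tested.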
